A study of Mus musculus with 4 samples.

How the data were processed

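Total RNA of mouse embryonic stem cells was extracted with Trizol, and 500 ng of each sample was turned into Cy3-labelled cRNA with Agilent's 1-colour protocol, per the labels' protocols. Each of 4 groups (wild type, L3mbtl2 knockout, knockout with empty vector, knockout with lentiviral L3mbtl2) was 1 array, and the groups were taken from the sample titles. The 4 arrays were on 1 slide, so slide and scan could not be a batch between groups.

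Per the file headers, the deposited scanner files hold intensity values made by Agilent Feature Extraction, whose version is 9.1 per the submitters' processing notes. The processed intensity used here is background-subtracted and spatially detrended within each array, with a positive surrogate for spots near background and no scaling between arrays, per the file headers. The raw mean, median and local background intensity of each spot are deposited beside it. Other columns used are flags of 0 or 1 set by the software, per the file headers. The authors also deposited a table of log2 values, which no header or label describes. Each of its 45015 values per array equalled log2 of the raw median spot intensity within 1e-06, so these log2 values are neither background-subtracted nor scaled nor centred, with column medians of 6.19 for wild type, 6.26 for knockout, 6.39 for empty vector and 6.34 for rescue.

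Control spots were left out, which left 43379 spots per array. Spots flagged as non-uniform, as outliers among repeats, or as having an uneven local background were also left out, which was 6 spots in wild type, 10 in knockout, 36 in empty vector and 21 in rescue. The last of these flags was added after a spot beside debris had been seen. Spots of 1 probe were averaged on the log2 scale, and each array's 75th percentile over probes was subtracted. Of 41109 probes, 22910 were named by accession and 6653 by symbol from the RefSeq gene table of the mouse genome given for this work, GRCm38.p6, and 3105 through an older symbol, which left 8441 without a gene name. The build behind the array's design is not given in the sources used here, so no coordinates are printed, and the table served only for names and for which genes share a chromosome. A gene took the value of its probe with the highest mean, out of 19490 genes, of which 8655 had several probes.

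A gene counted as higher or lower at a 2-fold difference between 2 arrays, with no p-value, since a comparison of 1 array with 1 array has no residual error of its own. A probe not well above background on 1 array of a comparison entered with a bound, as the brighter value over the higher of the dim value and the lowest signal well above background on that array, and a probe dim on both was not compared. Precision is limited by the number of arrays. Knockout against wild type and empty vector against rescue share no array, so their overlap was set beside that of independent lists. The 21 gene lists were fixed before the data were examined, and a list's median log2 ratio was given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Medians outside the central 95% are called outside the random range.

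The rule for named genes, also written before the data were examined, took L3mbtl2, the 12 genes higher and the 12 lower in both main comparisons with the largest smaller ratio, and the 5 highest and 5 lowest in empty vector against knockout and in rescue against wild type. It also took the 5 highest and 5 lowest in knockout against wild type that were under 1.2-fold or opposite in the other comparison, and up to 4 members of each list with the largest mean ratio. Symbols of predicted or clone-named genes were left out, and 2 genes that the rule took are not reported here.

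The alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50, the deposited log2 values, only probes well above background on all 4 arrays, no filter, the mean over a gene's probes, and thresholds of 1.5-fold and 3-fold. Another was limma's additive model of L3mbtl2 and vector with 1 residual degree of freedom, with genes at a Benjamini-Hochberg adjusted p under 0.05. The rule was tested on simulated arrays over the 16044 genes compared in both pairs. Noise was drawn from a normal distribution, with an SD from the median absolute deviation of empty vector against knockout, the most similar arrays. Changed genes were placed only among genes brighter than the median. The rule found 66 of 66 genes changed 3-fold and 66 of 66 changed 6-fold, 0 of 66 changed 1.5-fold and 0 of 15846 unchanged genes. limma found 66, 66, 23 and 34 of them, so unchanged genes were a larger share of its calls than its threshold of 0.05 allows. Changed dim genes, genes entered with a bound and outlying differences were not simulated, so the test does not cover them. Empty vector against knockout itself had 104 genes at least 2-fold apart. The 0 unchanged genes found in the simulation are therefore not an error rate of the rule on these arrays. Of 200 unchanged simulated lists of 25 genes, 10 lay outside the central 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.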

Results

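Gene expression was measured in mouse embryonic stem cells of a C57bl6/129 hybrid background, in which L3mbtl2 had been deleted and then put back. L3mbtl2 is a chromatin protein with malignant brain tumour domains and a subunit of PRC1.6, a variant Polycomb complex. Cells of 4 kinds were hybridised to 1 array each: wild type, L3mbtl2 knockout, knockout carrying an empty vector, and knockout carrying a lentiviral L3mbtl2 transgene, called rescue here. All 4 arrays lay on 1 slide. There were no replicates, so no difference between groups has a replicate check, and every value is given as a description of these arrays. On the array of wild-type cells 70.4% of the gene spots were well above background, against 71.0% for the knockout, 74.0% for the empty vector and 72.3% for the rescue, and no spot was saturated. Between repeated spots of the same probe, the log2 ratio of knockout to wild type had a median SD of 0.07 over 198 replicated probes, and this is the only technical error that the arrays give.

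L3mbtl2 itself was read by 2 probes, which differed on the rescue array. The brighter probe had a processed signal of 1796 on the wild-type array, 609 on the knockout array, 1156 on the array labelled empty vector and 634 on the array labelled rescue. After scaling, it was 3.30-fold lower in knockout than in wild type and 3.47-fold lower on the array labelled rescue than in wild type. On the array labelled empty vector it was 1.78-fold higher than on the array labelled rescue, opposite to what the labels imply for the transgene. The dimmer probe had signals of 51.6, 20.7, 40.4 and 99.1 in the same order, and was 4.37-fold higher on the array labelled rescue than in knockout. Whether either probe lies inside the deleted part or inside the transgene was not analysed here. Both probes were lower in knockout than in wild type, but alone they do not settle the label of the rescue array. That array had 817 genes at least 2-fold apart from wild type, against 2138 for the array labelled empty vector. Every direction drawn from the arrays labelled empty vector and rescue rests on their labels.

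**Figure D1:**
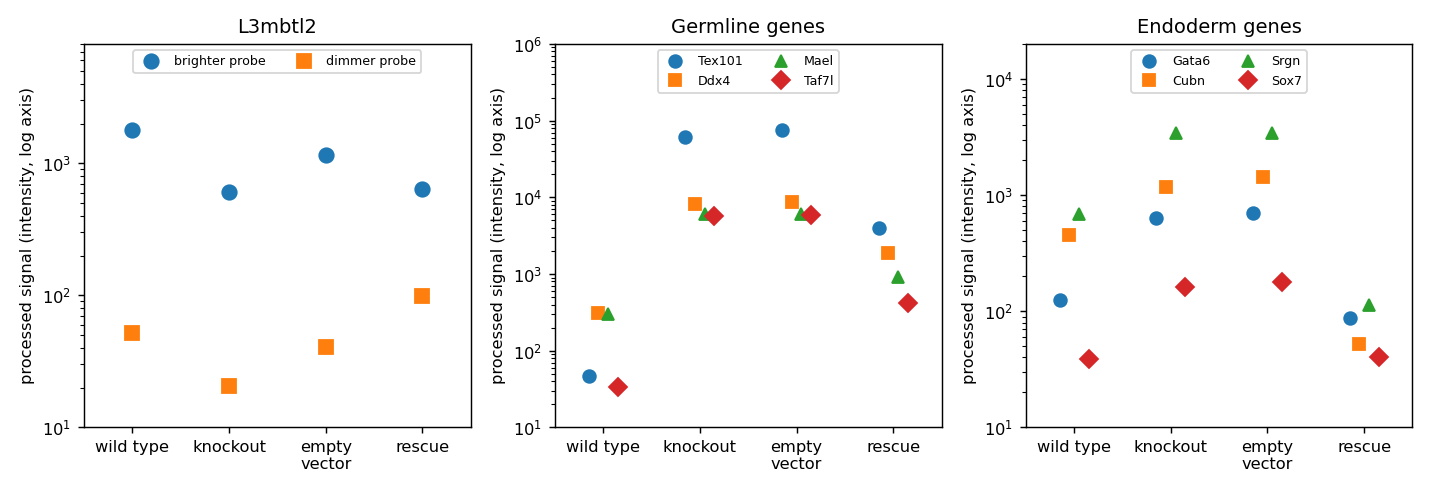
Processed signal (intensity, log axis) on each of the 4 arrays for both L3mbtl2 probes, 4 germline genes and 4 endoderm genes, with 1 point per array and small sideways offsets. The brighter L3mbtl2 probe reads 634 on the array labelled rescue and the dimmer one 99.1, while Tex101 lies at 46.1 in wild type, 61294 in knockout and 3956 in rescue.

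The first comparison asks which genes differ in cells that lack L3mbtl2. Genes known from the male germline were among the highest in knockout. Tex101, a surface glycoprotein of germ cells, was 1189-fold higher in knockout than in wild type, Rhox13, a homeobox gene of germ cells, 291-fold, and Taf7l, a germ cell paralogue of a general transcription factor subunit, 148-fold. Among the genes lower in knockout were Cldn4, a tight junction protein, by 16.1-fold, and Calml4, a calmodulin-like protein, by 15.8-fold. Of 16148 genes compared, 1272 were at least 2-fold higher and 922 at least 2-fold lower in knockout, while at 1.5-fold 2399 were higher and 2613 lower. Fibroblast markers moved with this comparison: the list fixed for feeder cells had a median log2 ratio of 1.84, with 22 of 26 members at least 2-fold higher. Genes of chromosome 1 also lay higher in knockout as a whole, with a median log2 ratio of 0.34 over 867 genes. With normexp background correction 904 genes passed the rule, and with the deposited log2 values 1043.

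The second comparison, of empty vector with rescue, asks what putting L3mbtl2 back did in cells of one genotype, and shares no array with the first. These germline genes were higher on the array labelled empty vector than on the array labelled rescue, Tex101 by 18.8-fold, Taf7l by 13.8-fold and Rhox13 by 9.37-fold. Endoderm genes stood beside them: Srgn, a proteoglycan core protein, was 29.5-fold higher, and Cubn, an endocytic receptor of visceral endoderm, 26.8-fold higher. Calml4 was 77.5-fold lower and Gtsf1l, a relative of a gametocyte factor, 11.9-fold lower. Of 16505 genes compared, 905 were at least 2-fold higher and 698 at least 2-fold lower. The fibroblast marker list had a median log2 ratio of 0.57 here. Normexp background correction gave 589 genes, 285 higher and 304 lower, and the deposited log2 values 693, 349 higher and 344 lower.

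Both comparisons moved together across genes. Of 16044 genes compared in both, 542 were at least 2-fold higher without L3mbtl2 in each, against 69.3 for independent lists, and 403 were lower in each, against 37.7. Normexp gave 174 and 173, against 9.39 and 7.30, and the deposited log2 values 208 and 193. Only 10 genes went opposite ways, against 102 for independent lists. Pearson's r between the 2 log2 ratios was 0.71 across genes, which are not independent replicates. When the arrays were instead paired by vector, as empty vector with knockout and rescue with wild type, 4 genes went the same way, against 1.79 for independent lists, and 11 opposite ways, against 1.598. Genes at least 2-fold higher in knockout than in wild type had a median log2 ratio of 1.48 there and 0.89 in empty vector against rescue, and 92.6% of these 1264 genes kept the sign. For the 913 lower genes the medians were -1.35 and -0.89, and 88.3% kept the sign. Both sets were selected on the first ratio, which alone can make the second smaller.

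**Figure D2:**
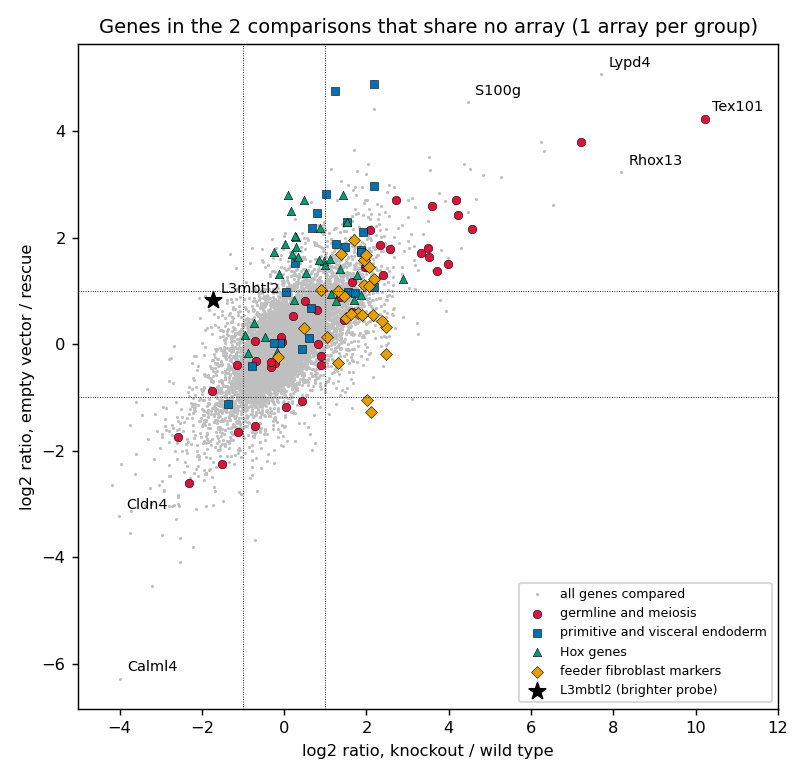
Each point is a gene, with its log2 ratio of knockout to wild type on the x axis and of empty vector to rescue on the y axis, 1 array per group, and dotted lines at 2-fold. Points in the upper right and lower left fields are the 542 genes higher and the 403 lower in both comparisons, while the brighter L3mbtl2 probe (star) lies at -1.72 and 0.83.

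Among the genes higher in both comparisons, several of those with the largest ratios are known from testis. Lypd4, which encodes a sperm membrane protein, was 209-fold higher in knockout than in wild type and 33.5-fold higher in empty vector than in rescue. Wild-type signals of Lypd4 and of S100g, given below, were 7.88 and 10.4. Both lay near the lowest signal well above background there, 4.95, so their folds over wild type are imprecise. Dmrtc2, a meiotic transcription factor, was 75.6-fold and 13.9-fold higher, and Hsf5, a heat shock factor of spermatocytes, 38.4-fold and 8.73-fold. Spaca1, an acrosome protein, was at least 23.1-fold higher in knockout, since it was not well above background in wild type, and 9.74-fold higher in empty vector. Rbmy, a Y-linked family of near-identical copies that a probe cannot separate, was at least 11.4-fold higher in both. The remaining genes of this set were S100g, a calcium-binding protein, at 22.1-fold in knockout and at least 23.2-fold in empty vector, Kcns1, a potassium channel subunit, at 20.8-fold and 10.4-fold, Plekhg4, a guanine nucleotide exchange factor, at 28.5-fold and 8.99-fold, and Timd2, at least 11.6-fold and at least 9.58-fold. A bound of this kind sets the brighter array against the higher of the dim probe's own value and the lowest signal well above background on its array.

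Among the genes lower in both comparisons, Cldn4 was 9.36-fold lower in empty vector than in rescue. Trmo, a transfer RNA methyltransferase, was 10.4-fold lower in knockout than in wild type and 8.08-fold lower in empty vector than in rescue. Bdh2, a dehydrogenase, was 7.58-fold and 6.73-fold lower, Clstn3, a calsyntenin, 9.60-fold and 6.48-fold, and Lnx1, a ubiquitin ligase, 6.65-fold and 8.19-fold. Rhox6, a homeobox gene of the same X-linked cluster as Rhox13, was 7.57-fold and 6.72-fold lower. Gtsf1l was 7.84-fold lower in knockout, Fam178b, on chromosome 1, 6.39-fold and 8.07-fold lower, Zscan5b at least 9.43-fold and at least 8.03-fold lower, and Afm, a vitamin E carrier, at least 6.90-fold and 8.19-fold lower. Where a gene of the same-direction set had further probes well above background on all 4 arrays, 248 of 279 such probes had the same sign in both comparisons.

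Of 43 germline and meiosis genes compared, 21 were at least 2-fold higher in knockout than in wild type and 6 lower, with a median log2 ratio of 0.89. In empty vector against rescue 18 of 44 were higher and 7 lower, with a median of 0.56, and 18 were higher in both comparisons. Both medians lay above all 10000 random lists of the same size matched on mean expression. Ddx4, the RNA helicase of germ cells, was 23.5-fold higher in knockout and 4.49-fold higher in empty vector, and Mael, a piRNA pathway protein whose gene lies on chromosome 1, 18.1-fold and 6.52-fold. The 6 members lower in knockout included Hormad1 and Syce1, parts of the meiotic chromosome axis and synaptonemal complex, at 4.94-fold and 2.85-fold, and Prdm1, a regulator of germ cell fate, at 5.96-fold. These 3 were chosen after their values were seen. The list was fixed with knowledge of PRC1.6 and holds genes known to respond to it, so its direction is not independent of earlier work.

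Genes of primitive and visceral endoderm, the extraembryonic lineage that stem cells can form, were also higher without L3mbtl2. In knockout against wild type 13 of 24 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.12, and in empty vector against rescue 14 of 25 were higher and 2 lower, with a median of 1.52. Gata6, a transcription factor that drives this lineage, was 4.55-fold higher in knockout and 7.78-fold higher in empty vector. A dimmer Gata6 probe had log2 ratios of -0.35 and -0.40, and another dimmer probe 1.77 and 2.75. Sox7, another factor of it, on chromosome 14, was 3.78-fold and 4.32-fold higher, Srgn 4.53-fold higher in knockout, and Cubn 2.34-fold. Hox genes, which pattern the body axis, went the same way: 11 of 35 were at least 2-fold higher in knockout and none lower, with a median of 0.47, and 23 of 33 were higher in empty vector, with a median of 1.52. Hoxa11 was 7.39-fold higher in knockout and 2.33-fold in empty vector, Hoxa10 3.94-fold and 2.87-fold, and Hoxb13 2.67-fold and 6.96-fold. Hoxb8 was at least 2.87-fold and at least 4.91-fold higher. The Hox medians lay above 99.98% and 100% of matched random lists, but many Hox signals were dim.

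The fibroblast marker list, fixed because stem cells are often grown on fibroblasts, was the highest of 21 lists in knockout against wild type. S100a4 was 3.94-fold higher in knockout and 3.19-fold higher in empty vector, Acta2, smooth muscle actin, 3.26-fold and 3.85-fold, Cav1, caveolin, 4.18-fold and 2.74-fold, and Lox, which cross-links collagen, had log2 ratios of 1.94 and 1.58. These 4 were named for the largest mean of both ratios. In empty vector against rescue 9 of 25 members were at least 2-fold higher and 2 lower, Mmp3 and Lum. Among other members, picked after their values were seen, Col3a1 was 5.54-fold higher in knockout and 1.14-fold lower in empty vector. Dcn was 2.48-fold higher and 1.28-fold lower. Of the Y-linked genes, at low signal, Eif2s3y was 4.15-fold higher in knockout and 1.69-fold higher in empty vector, Ddx3y 3.93-fold and 1.46-fold, and Kdm5d at least 2.24-fold and 1.52-fold, while Uba1y was 5.75-fold and 1.01-fold higher, and Rbmy at least 11.4-fold in both. Xist, which silences an X chromosome, was 1.40-fold and 1.79-fold higher at signals between 6.44 and 11.8. The median of the Y-linked genes and Xist was 1.16 in knockout against wild type and 0.60 in empty vector against rescue.

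Genes that answer to BMP and TGF-beta, signals that also act on fibroblasts, had medians of 0.87 and 0.44, with 9 and 8 of 22 members at least 2-fold higher and none lower. Inhba, an activin subunit, was 4.20-fold higher in knockout and 3.38-fold higher in empty vector, Ccn1, a matrix protein, 3.94-fold and 3.29-fold, and Fst, which binds activin, 3.01-fold and 2.52-fold. Of p53 targets and cell cycle inhibitors 3 of 24 were at least 2-fold higher in knockout and 1 lower, and the medians were 0.27 and 0.37. Cdkn1a, the inhibitor p21, was 2.32-fold and 1.94-fold higher, Cdkn2b 2.79-fold and 1.72-fold, and Cdkn2a had log2 ratios of 0.59 and 1.39, while Bbc3, a cell death gene, was 2.69-fold and 1.57-fold lower. Cell cycle genes had medians of -0.20 and -0.33, of which the second lay at percentile 0.01 of matched random lists. Ccne1 and Mycn were 1.87-fold and 2.63-fold lower in knockout, and Ccnd2 and Ccnd1 2.89-fold and 1.84-fold higher.

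The pluripotency network had a median of -0.04 in knockout against wild type, inside the central 95% of matched random lists, with 5 of 28 members at least 2-fold higher and 1 lower. In empty vector against rescue its median was -0.30, at their percentile 0.2. Dppa3, a factor of the early embryo and germ cells, was 6.92-fold lower in knockout and 5.55-fold lower in empty vector. Lefty2, a Nodal antagonist on chromosome 1, was 2.49-fold and 2.14-fold higher, Lefty1 beside it 1.23-fold and 3.44-fold, and Tcl1, an Akt cofactor, 2.76-fold and 1.71-fold. In the list of L3mbtl2 itself and its PRC1.6 partners the medians were -0.13 and -0.24, both inside the range of random lists. E2f6, which brings the complex to DNA, was 2.59-fold and 2.04-fold higher without L3mbtl2, Tfdp2 2.15-fold and 2.01-fold lower, Tfdp1 1.49-fold and 1.51-fold lower, and Hdac2 1.77-fold and 1.17-fold higher. Other Polycomb proteins had medians of -0.27 and -0.21, inside that range too, with Cbx8 3.39-fold and 2.40-fold higher, Bmi1 2.43-fold and 2.19-fold higher, Cbx7 1.73-fold and 2.13-fold lower, and Phf19 1.71-fold and 1.85-fold lower.

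Among lists on metabolism, stress and ribosomes, only hypoxia and glycolysis genes lay below the random range in both main comparisons. Hypoxia and glycolysis genes had medians of -0.46 and -0.43, both below all matched random lists, and Bnip3, a mitophagy receptor induced by hypoxia, was 4.57-fold lower in knockout and 2.30-fold lower in empty vector. Egln3, an oxygen sensor, was 3.35-fold and 2.29-fold lower, Ankrd37 3.18-fold and 2.19-fold lower, and Pfkfb3 2.15-fold and 1.77-fold higher. Stress and unfolded protein response genes had medians of -0.29 and -0.21, of which the first lay outside the central 95%. Psat1, of serine synthesis, was 2.85-fold and 2.69-fold lower, Chac1 2.78-fold and 2.67-fold, Trib3 2.57-fold and 2.97-fold, and Nqo1 2.66-fold and 1.80-fold higher. Cholesterol synthesis genes had a median of -0.38 in knockout, at percentile 0.13 of random lists, and -0.09 in empty vector, inside the random range. Mvd was 1.82-fold lower in knockout, Msmo1 1.53-fold, Pmvk 1.52-fold, and Hsd17b7, on chromosome 1, 1.70-fold higher. Ribosomal proteins had medians of -0.26 and -0.16, inside the random range, with Rpl4 1.53-fold, Rpl37 1.52-fold, Rps6 1.38-fold and Rpl3 1.33-fold lower in knockout.

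Imprinted genes had a median of -0.65 in knockout against wild type, below all matched random lists, with 8 of 25 members at least 2-fold lower and 2 higher, but 0.00 in empty vector against rescue. Nnat, a membrane protein of neural development, was 4.09-fold and 2.72-fold lower, but also 3.33-fold lower in empty vector than in knockout and 5.01-fold lower in rescue than in wild type. Phlda2, a growth regulator of placenta, was 2.51-fold lower in knockout, Slc22a18 2.04-fold and 3.03-fold, and Mest 1.62-fold and 12.8-fold. Mesoderm and primitive streak genes had medians of 0.27 and 0.10, with Cdx1 6.25-fold higher in knockout, and T (brachyury), Fgf8 and, on chromosome 14, Bmp4 3.54-fold, 3.99-fold and 1.34-fold lower. Median centring moved the first of these medians to 0.26 and inside the random range. Neural and ectoderm genes had medians of -0.11 and 0.00, with Map2, on chromosome 1, 2.63-fold and Sox11 2.12-fold lower in knockout, Zic1 1.98-fold higher and Pax3, on chromosome 1, at least 1.39-fold higher. Trophoblast genes had medians of 0.01 and 0.37, with Esx1 5.08-fold and Hand1 1.91-fold higher in knockout, Gata3 at a log2 ratio of 1.59 and Krt7 2.82-fold lower. Interferon-stimulated genes had medians of 0.15 and 0.31, with Usp18 4.72-fold, Ifih1 3.07-fold and Cxcl10 2.39-fold higher in knockout and Oas1a 1.58-fold lower. For 2-cell-like genes the medians were -0.01 and 0.77, with Zscan4c 2.24-fold and 3.25-fold higher, Usp17la 2.96-fold higher in empty vector, and Usp17lb and Arg2 dim. The Zscan4 and Usp17l families hold near-identical copies.

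**Figure D3:**
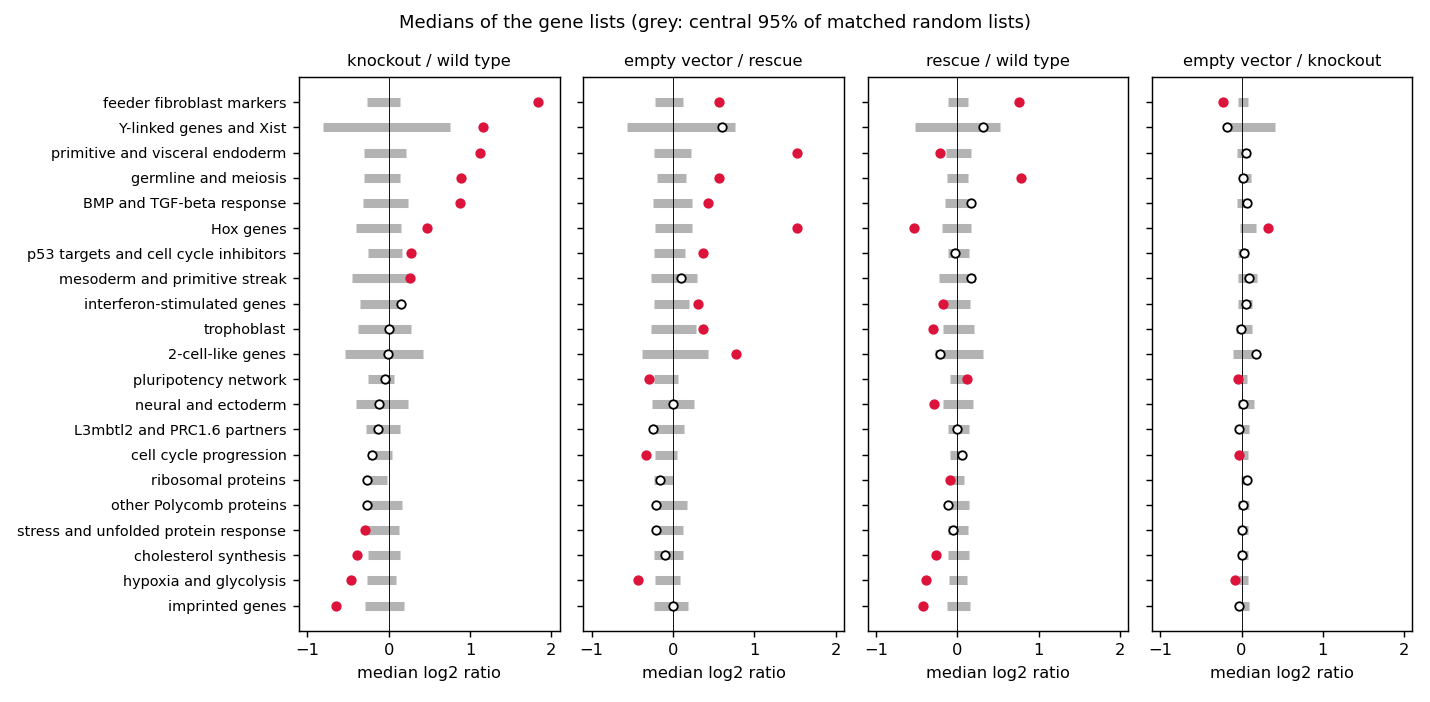
Median log2 ratio of each of the 21 gene lists (points) in 4 comparisons of 1 array with 1 array, with grey bars for the central 95% of 10000 random lists matched on mean expression. Filled points lie outside the bar. In knockout against wild type the medians run from -0.65 for imprinted genes to 1.84 for fibroblast markers.

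Some genes differed between knockout and wild type and were under 1.2-fold apart, or opposite, in empty vector against rescue. Kank4, which binds actin regulators, was 9.59-fold higher in knockout and 1.15-fold higher in empty vector, and Col6a3, a collagen chain on chromosome 1, 5.84-fold and 1.12-fold. Uba1y, a Y-linked gene, was 5.75-fold higher in knockout and 1.01-fold higher in empty vector, and Oaf was 5.55-fold higher in knockout. Agtr2, an angiotensin receptor, was 8.64-fold higher in knockout and 2.04-fold lower in empty vector. Wild-type signals of Agtr2, Oaf and Uba1y were 8.28, 8.19 and 8.37, near the lowest signal well above background there, 4.95. The lowest of this kind were Rassf9 at 6.69-fold, Olfr603 at 6.43-fold, Pdlim3 at 4.42-fold, Cysltr1 at 4.19-fold and Cyp2j13 at 4.14-fold lower in knockout. A dimmer Cyp2j13 probe, not well above background in wild type, had a log2 ratio of at least 1.23.

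Empty vector against knockout served as a yardstick, since by their labels both carry the deletion and no transgene. Both L3mbtl2 probes were higher on the array labelled empty vector than on the knockout array, the brighter by 1.69-fold and the dimmer by 1.74-fold. Here 63 of 16342 genes were at least 2-fold higher and 41 at least 2-fold lower, and under quantile normalization the split turned to 36 higher and 59 lower. Normexp gave 0 higher and 6 lower, and the deposited log2 values 0 and 8. Mest, an imprinted gene expressed from the paternal copy, was 12.4-fold lower in empty vector than in knockout, at signals of 244 and 2697. Gkn2 was 12.1-fold lower, Speer5-ps1, of a multicopy family, 3.58-fold, Olfr491 at least 4.34-fold and Lipm at least 3.76-fold. The highest were dim in empty vector and not well above background in knockout: Trim30b at least 8.33-fold, Sorcs3 at least 7.55-fold, Doc2b at least 5.92-fold, Prg3 at least 4.59-fold and Igbp1b at least 3.05-fold. Of the germline and endoderm lists no member was 2-fold apart, while the fibroblast list had a median of -0.23 and the Hox list one of 0.33, both outside the range of random lists. So were smaller medians of -0.08 for hypoxia and glycolysis genes, -0.05 for the pluripotency network and -0.03 for cell cycle genes. Limiting the count to probes well above background on all 4 arrays left 32 genes.

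Rescue against wild type asks how far the cells with the transgene remained from cells that never lost the gene. Of 16180 genes, 485 were at least 2-fold higher and 332 at least 2-fold lower on the array labelled rescue, against 178 and 103 with normexp and 202 and 128 with the deposited log2 values. Germline genes were still high: Tex101 was 70.0-fold above wild type, Rhox13 32.3-fold, Taf7l 9.96-fold and Tex13b at least 13.7-fold, and 16 of 42 list members were at least 2-fold higher and none lower. Crocc2, on chromosome 1, was at least 9.15-fold higher. Endoderm genes lay below wild type, with a median log2 ratio of -0.21 and 6 of 24 members at least 2-fold lower. Cubn was 10.5-fold lower and Srgn 7.42-fold lower, and Olfr603, Iqcf3 and Trim69 were 6.76-fold, at least 6.39-fold and at least 5.94-fold lower. Hox genes also lay lower, with a median of -0.53 and 6 of 30 at least 2-fold lower. Imprinted genes at -0.42, hypoxia and glycolysis genes at -0.38 and cholesterol synthesis genes at -0.26 lay below the random range too. So did trophoblast genes at -0.30, neural and ectoderm genes at -0.29, interferon-stimulated genes at -0.18 and ribosomal proteins at -0.09. The pluripotency network lay above it, at 0.13. Fibroblast markers were higher, with a median of 0.76 and 9 of 25 at least 2-fold higher, and chromosome 1 had a median of 0.39 and chromosome 14 one of 0.24.

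**Figure D4:**
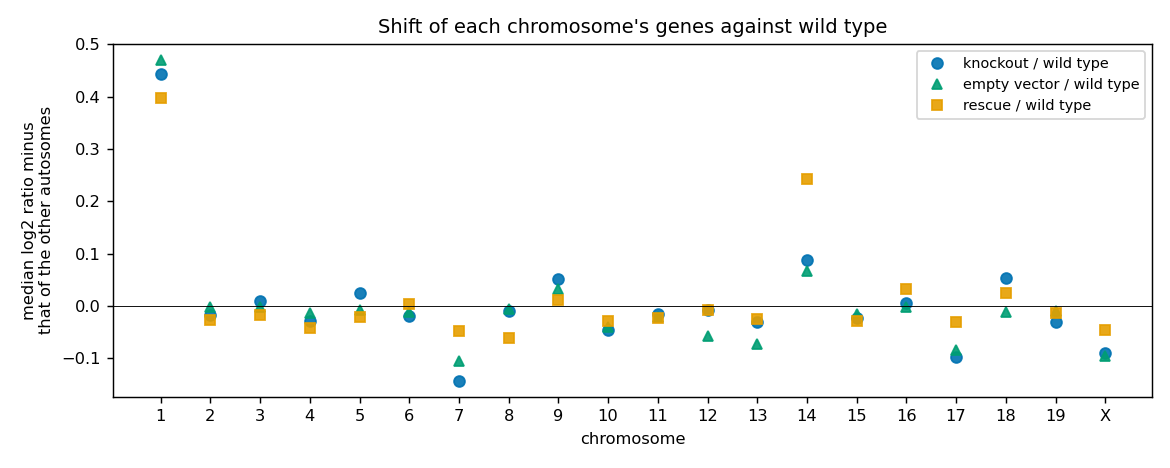
Median log2 ratio to wild type of each chromosome's genes minus that of the other autosomes, for knockout, empty vector and rescue, 1 array each, over genes well above background on all 4 arrays. Chromosome 1 lies at 0.44, 0.47 and 0.40, and chromosome 14 at 0.24 in rescue.

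How much of the knockout's difference was seen again in empty vector against rescue was described for the 7 lists with at least 5 members 2-fold higher in knockout. For the 21 germline genes at least 2-fold higher in knockout, each gene's log2 ratio in empty vector against rescue was taken as a percentage of its own in knockout against wild type, and the median of these percentages was 54.3%, while 13 of them were still at least 2-fold above wild type on the array labelled rescue. For the 13 endoderm genes the median percentage was 122%, with none still 2-fold above wild type and 3 at least 2-fold below. The 11 Hox genes gave 76.9% and the 9 BMP and TGF-beta genes 85.0%, with 1 of each still 2-fold above wild type. The 22 fibroblast markers gave 33.9%, and 9 of them were still 2-fold above. The 5 interferon-stimulated genes gave 53.6%, and the 5 pluripotency genes -30.9%, the other way. Members were selected by the same ratio that each percentage is divided by, which alone can lower the percentages. Rescue against wild type shares the wild-type array with that selection, which can keep genes above wild type. Differences between lists were not tested, since each rests on the same 4 arrays.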

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

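All tests of explanations in this part were chosen after the results were seen.

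The brighter L3mbtl2 probe was lower in knockout than in wild type by a log2 ratio of -1.72 but higher in empty vector than in rescue by 0.83, opposite signs under the same contrast. The dimmer probe read 4.37-fold higher on the array labelled rescue than on the knockout array. An exchange of the empty vector and rescue arrays would place the former nearer to wild type, but the array labelled empty vector had 2138 genes 2-fold apart from wild type and the array labelled rescue 817, and the array labelled empty vector differed from knockout by 104 genes. Noise of a dim spot is argued against by the dimmer probe's log2 ratio of 2.13 between rescue and knockout, since repeated spots of a probe differed with a 95th percentile SD of 0.32. A candidate explanation is that the brighter probe lies in a part of the transcript that the transgene lacks: the 2 probes' rescue to wild type ratios differ by 2.44, and their places in the transcript were not analysed here, so this stays open, as does the higher signal of both probes in empty vector than in knockout.

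Between the main comparisons 10 genes were at least 2-fold apart in opposite directions, and this difference was not tested. Agtr2 had a log2 ratio of 3.11 in knockout against wild type and -1.03 in empty vector against rescue. The others, named after their values were seen, were Rgcc, Mmp3, Lum, Rapgef3 and Prss27, higher in knockout and lower in empty vector, and Ephx3, Duxbl1, Gm7056 and 4930470G03Rik the other way. Mmp3 and Lum are members of the fibroblast marker list.

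Probes without a gene name, which no comparison of genes used, also went the same way in both comparisons more often than independent lists would. Of 3900 such probes compared in both, 136 were at least 2-fold apart in the same direction, against 14.6 for independent lists and 2 when the arrays were paired by vector.

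Fibroblast markers were higher in knockout than in wild type, with a median log2 ratio of 1.84, and were also higher in rescue, by 0.76. The most abundant were S100a4 at 13101 in wild type and 57661 in knockout, Tagln at 10138 and 29442, Vim at 7861 and 27082, and Col1a2 at 3587 and 14886, and 25 of 26 markers were already well above background in wild type. More feeder cells as part of the cause could bring Y-linked transcripts in step, if feeders were male and the stem cells had no Y chromosome. Eif2s3y and Ddx3y had signals of 31.7 and 10.7 in wild type and 147 and 46.8 in knockout. The X-linked genes Eif2s3x and Ddx3x had 7347 and 5691 in wild type. The mean of Eif2s3y and Ddx3y lay within the markers' median absolute deviation in 3 of 4 comparisons. In rescue against wild type it was 0.408 from the median against a deviation of 0.406. As first written, this test counted that as not fitting. Its bound was then widened by the spread between repeated spots, after that outcome was seen, which leaves this open. Other Y-linked genes, which it did not use, differed among themselves. In empty vector against rescue, where the markers had a median of 0.57, Kdm5d had a log2 ratio of 0.60, Uba1y 0.02 and Rbmy at least 3.51. In rescue against wild type Uba1y had 1.90. Feeder cells as the whole cause were also tested, with a rewrite of that test after its first outcome, but it rested on 1 marker and an assumed profile and was dropped. The labels name no feeder cells, sort or sex of the cells, and an effect of L3mbtl2 on these genes is an untested explanation that stays open too.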

How the results depend on the processing

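No pairing of replicates was possible because each group is 1 array and the labels carry no shared numbers. Leaving out an array was not possible because each group is 1 array. limma's additive model, given below, compares within vector status instead. The count without genes of chromosomes 1 and 14 and the one that kept spots with an uneven background were chosen after seeing the data. All 5 counts stayed within 1.5 times, but each change touched few genes or spots, so a larger move was unlikely beforehand. Without these chromosomes, 14686 of 16148 genes were still compared in knockout against wild type. Of chromosome 1 genes compared, 15.9% were at least 2-fold higher in knockout, against 7.30% on the other autosomes. Counts below follow the order knockout against wild type, empty vector against rescue, empty vector against knockout, rescue against wild type, and same direction in both, where the main values were 2194, 1603, 104, 817 and 945. Normexp gave 904, 589, 6, 281 and 347, and the deposited values 1043, 693, 8, 330 and 401: both leave background or an offset in the values, which shrinks ratios of dim probes. For normexp, spots with a flagged background were left out of the fit. A 1.5-fold threshold gave 5012, 4083, 604, 2566 and 2478, and a 3-fold one 842, 516, 17, 187 and 274. Only probes above background on all arrays gave 32 in empty vector against knockout. With no filter and no bounds, 2 choices changed at once, that count was 662, and rescue against wild type 1419. Quantile normalization, median centring and the mean over probes kept all 5 counts within 1.5 times. limma's additive model gave 792 genes for L3mbtl2, 446 higher and 346 lower, and 0 for the vector. For the vector, 398 genes had an unadjusted p under 0.05, a smaller share of the 16044 tested than the 0.05 given by chance. With 1 residual degree of freedom, the 0 does not show that the vector had no effect. The smallest limma adjusted p for L3mbtl2 was 0.041, so all 792 genes lay close under the threshold of 0.05. In the simulation above, limma called more unchanged genes than that threshold allows. This model takes knockout and empty vector, and wild type and rescue, as repeats apart from the vector. Of 588 list medians recomputed, 560 stayed on their side of the random range, 15 moved inside, 12 moved outside and 1 reversed: cell cycle genes in empty vector against knockout, 0.0080 with the mean over probes; the cause was not tested. Of 3388 ratios of named genes, 195 fell under 2-fold and 7 passed it, and 0 that were first at least 2-fold reversed. These genes were mostly taken for large ratios on the same arrays, so a reversal was unlikely beforehand. Ratios that could not be compared under an alternative were left out of this tally. A change of sign was counted only for ratios first at least 2-fold and for medians first outside the random range. L3mbtl2 in empty vector against rescue, with log2 ratios of 0.83 and -1.33 at its probes, was therefore not counted.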

Other observations

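All tests of explanations in this part were chosen after the results were seen.

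Within the X-linked Rhox homeobox cluster, 8 genes had a probe, and they went both ways without L3mbtl2. Rhox5, a homeobox gene of the embryo and testis, had a processed signal of 11728 in wild type, 3543 in knockout, 2776 in empty vector and 14509 in rescue, and Rhox9 signals of 1928, 317, 380 and 2069 in the same order. Rhox5 was thus 3.70-fold lower in knockout and 5.37-fold lower in empty vector than in rescue, and Rhox9 6.80-fold and 5.59-fold, beside Rhox6. Rhox13 and Rhox2a were 291-fold and 6.51-fold higher in knockout, and Rhox2a was 1.23-fold higher in empty vector than in rescue. These directions were the same under quantile normalization and median centring. Rhox5, Rhox6 and Rhox9 lay within 1.14-fold of wild type on the array labelled rescue, while Rhox13 stayed 32.3-fold above. Members of the cluster are similar in sequence, and all but Rhox6 and Rhox13 were chosen after their values were seen.

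Genes of chromosome 1 were higher than wild type on all 3 knockout-derived arrays, by 0.44 more than the other autosomes in knockout, 0.47 in empty vector and 0.40 in rescue, and genes of chromosome 14 by 0.24 in rescue. The 17 other autosomes lay between -0.14 and 0.05 in knockout and between -0.06 and 0.03 in rescue, and chromosome 14 lay at 0.09 in knockout and 0.07 in empty vector. Chance or brightness is argued against by a percentile of 100 among random lists matched on mean expression, for chromosome 1 in knockout and for chromosome 14 in rescue. Smaller shifts can also lie at the edge of these lists: chromosomes 7 and 17 were at percentile 0 in knockout, by -0.14 and -0.10, and chromosomes 7 and 8 in rescue, by -0.05 and -0.06. Scaling is argued against by differences that remained under quantile normalization, 0.45 for chromosome 1 in knockout and 0.24 for chromosome 14 in rescue. An extra copy of chromosome 1 in knockout-derived cells, and of chromosome 14 in rescued cells, may account for this: with each chromosome split in order into 3 parts of equal gene number, the lowest part of chromosome 1 lay 0.41 above the other autosomes in knockout, and that of chromosome 14 lay 0.23 above in rescue. Whether the shifts are as large as an extra copy would give was not tested. Genomic DNA was not analysed here, so an extra copy remains a hypothesis, and no biological explanation through L3mbtl2 was tested beyond noting that the rescue array kept the shift of chromosome 1.

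On the array labelled empty vector, 9 spots had a local background over 60, against 0 on each other array. The spot for Ncan, a brain proteoglycan, had a local background of 14053.5 there against 36.5 in wild type, and was left out as uneven.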
